A study of Homo sapiens with 6 samples.

How the data were processed

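RNA from 786-O cells was extracted with Trizol and sequenced as BGISEQ-500 libraries, per the labels' protocols, in 3 Control and 3 siTEAD4 libraries. The authors deposited 1 table per library with 18126 gene symbols, in the same order in all 6, and 1 value per symbol in FPKM (fragments scaled by gene length and by the mapped fragments of the library), rounded to 2 decimals, per the file headers. The value column of Control 1 has no unit in its header and was taken as FPKM because its symbols, decimals and range match the other 5. The genome build was GRCh38, per the submitters' processing notes; the aligner, the counting tool, the annotation, the treatment of strand and any filter are not given in the sources used here. Groups were taken from the sample titles. The headers of the value columns read "Tead_Inhibitor" for the libraries labelled siTEAD4 and "Vehicle" for Control 2 and Control 3, and which treatment these libraries received could not be settled from the values.

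FPKM keeps no depth. Low values were searched for the steps of single reads: of 235 ratios in 121 low genes, 25.5% lay within 0.1 of a whole multiple, where an even spread gives 20%, so whole reads were not recovered and no counting interval is given. No 2 libraries held identical values, since at most 0.684% of tested genes had equal values in any pair. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. FPKM values also depend on the total of each library, so a change in a few abundant genes shifts all others, and reads shared between near-identical genes (HSPA1A and HSPA1B, AKR1C1 to AKR1C3, AKR1B10 and AKR1B15, FTL and FTH1 and their pseudogenes, CXCL1 to CXCL3, C4A and C4B, SAA1 and SAA2, histones) can be split between them in ways not given here.

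Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 11411 in all. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with group as the only term. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes under 0.05 were called. "Adjusted over the list alone" means the same adjustment within one list. TEAD4 was also tested by an exact two-sided permutation of its mean FPKM. Levels are means ± SD of FPKM over 3 libraries, and intervals are 95% intervals from limma.

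Before the data were examined, 29 gene lists were fixed, and 545 of their 562 symbols were found, with older symbols matched. The 25 lists with at least 5 tested genes were compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 25 lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera takes its degrees of freedom from the libraries, so leaving out a library raises its p-values at the same effect. A further 6 lists were written after the data had been seen. The genes named were fixed by rule: TEAD4, TEAD1, TEAD2, TEAD3, YAP1 and WWTR1; the 10 largest rises and 10 largest falls among called protein-coding genes whose higher group mean reached the median (13.6 FPKM) and whose groups did not overlap; up to 4 called members per list with the largest change; and CCN1, CCN2, ANKRD1, AXL, NFKBIA, TNFAIP3, CXCL8, IL6, CCL2 and BIRC3. Other genes named, such as members that moved against their list or completed a small count, were chosen after their values were seen. Some genes that the rule picks are not reported here. Coordinates, transcript lengths and GC content came from GENCODE release 29 on GRCh38, with 17879 of 18126 symbols matched, and 11357 of the tested genes (99.5%) had a length.

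Alternatives fixed before the data were examined were a replicate block, leaving out each library, rescaling to one median, an unweighted TMM-like scaling, quantile normalization, no filter or one of 5 FPKM, pseudocounts of 0.1 and 5, limma without the trend or with robust eBayes, stricter thresholds, and the other set tests. Removal of each library's trend with transcript length and GC content (natural splines with 5 degrees of freedom each) was added after the data had been seen.

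The fit was tested on simulated data for this comparison, with 11312 genes passing the filter and the means and group SDs of the real genes. Of 50 genes changed by each fold, 6% were recovered at 1.25-fold, 48% at 1.5-fold, 74% at 2-fold and 98% at 4-fold. Of 125 genes called there, 12 (9.6%) were unchanged, above the 5% aimed at, so called genes near the threshold may be less certain than their adjusted p states. Only 200 genes were changed there, while 5123 of 11411 were called in the data. The adjustment was therefore stricter in the simulation. Its recovered and unchanged shares are not rates for the real comparison. Of 25 unchanged lists 0 were called, and a list shifted by 0.5 on the log2 scale was recovered. Genes varied independently there and no library carried a length or GC trend. The list result therefore does not carry over to real lists, whose genes can vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.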

Results

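RNA was sequenced from 786-O cells, an established human clear cell renal carcinoma line, in 6 libraries. By the labels, 3 libraries came from cells transfected with a control (Control) and 3 from cells transfected with an siRNA against TEAD4 (siTEAD4). TEAD4 is a DNA-binding partner of the coactivator YAP, and the series title names YAP, a complex of TEAD4 with NF-kB, and the growth of this tumour type. Each library is a list of FPKM values for 18126 gene symbols, with 15676 to 15857 symbols above 0 per library. The values carry no read counts, so the depth of each library is unknown. The headers of the value columns disagree with the labels: those of the 3 siTEAD4 libraries read "Tead_Inhibitor", and those of Control 2 and Control 3 read "Vehicle". Groups follow the labels throughout, and every direction given for siTEAD4 holds for the libraries labelled siTEAD4, whichever treatment they received.

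The first question was whether the targeted transcript was lower. TEAD4 (chromosome 12, 2959330 to 3040673, plus strand, GRCh38) stood at 12.52, 16.99 and 11.28 FPKM in Control 1, 2 and 3, and at 8.92, 7.65 and 7.52 FPKM in siTEAD4 1, 2 and 3. The means were 13.6 ± 3.00 and 8.03 ± 0.774 FPKM (SD, n = 3 each), so the siTEAD4 libraries held 59.1% of the Control level. The log2 fold change was -0.68 ± 0.143 (SE), with a limma Benjamini-Hochberg adjusted p of 0.00521. A two-sided exact permutation test of the 3 against 3 libraries gave p = 0.1, the smallest it can give. TEAD4 was not among the largest falls, since 827 genes past the threshold fell by more. The other family members did not pass the limma test: TEAD1 had a log2 fold change of -0.35 (adjusted p = 0.161) and TEAD3 one of -0.21 (adjusted p = 0.0845). TEAD2 was below the expression filter, at 0.580 ± 0.159 FPKM in Control and 0.160 ± 0.0436 FPKM in siTEAD4 (SD, n = 3). The coactivator genes YAP1 (0.03, adjusted p = 0.886) and WWTR1, which encodes TAZ (0.16, adjusted p = 0.174), did not pass either. Single libraries decided some of these: without Control 2, TEAD1 passed (-0.59, adjusted p = 2e-04), as it did with each library's length and GC trend removed, an alternative chosen after seeing the data (-0.37, adjusted p = 0.00923), and without Control 1 so did TEAD3 (-0.25, adjusted p = 0.0454) and WWTR1 (0.23, adjusted p = 0.0456). TEAD3 also passed when each library was rescaled to one median (-0.27, adjusted p = 0.0425) or given TMM-like scaling (-0.27, adjusted p = 0.0381).

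**Figure D1:**
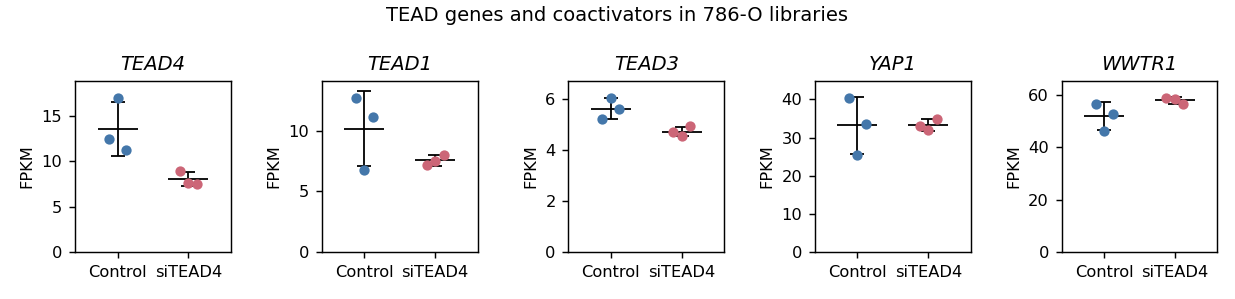
FPKM (vertical axes, from 0) of TEAD4, TEAD1, TEAD3, YAP1 and WWTR1 in the 3 Control and 3 siTEAD4 libraries; each point is 1 library, and bars give the mean ± SD. The 3 siTEAD4 libraries lie at 7.52 to 8.92 FPKM for TEAD4, below the 3 Control libraries at 11.28 to 16.99.

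Across the transcriptome, the detoxifying enzyme genes AKR1B10 and HMOX1 led the rises in the siTEAD4 libraries, and genes of the extracellular matrix and targets of NF-kB were among the largest falls. AKR1B10, an aldo-keto reductase, went from 32.8 ± 2.64 to 764 ± 10.5 FPKM (SD, n = 3 each), and HMOX1, the heme-degrading enzyme heme oxygenase 1, from 17.3 ± 1.52 to 312 ± 12.2 FPKM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 3.09 ± 0.466 to 53.7 ± 3.11 FPKM. The proteoglycan gene VCAN fell from 110 ± 5.32 to 10.2 ± 0.594 FPKM, and FN1, which encodes fibronectin, from 1829 ± 398 to 253 ± 1.10 FPKM. The chemokine gene CCL2 fell from 21.8 ± 1.26 to 2.28 ± 0.658 FPKM.

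By the rule fixed for naming genes, the 10 largest rises among well-expressed protein-coding genes were AKR1B10 (log2 fold change 4.50), HMOX1 (4.10), ANGPTL4 (3.75), OSGIN1 (2.52), NQO1 (2.11), IL11 (2.11), TMEM158 (2.00), SRXN1 (1.99), DUSP5 (1.87) and SQSTM1 (1.86). NQO1 encodes a quinone reductase, SRXN1 a sulfiredoxin, and SQSTM1 the autophagy receptor p62. The 10 largest falls were VCAN (-3.31), FN1 (-2.82), CCL2 (-2.81), VCAM1 (-2.78), TNC (-2.57), COL4A1 (-2.46), COL4A2 (-2.40), CDH6 (-2.35), CXCL1 (-2.29) and COL8A1 (-2.23). Limma's adjusted p values for these 20 genes lay between 2.21e-08 and 1.12e-05. In each of them the 3 libraries of one group all lay above the 3 of the other, which the naming rule required.

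**Figure D2:**
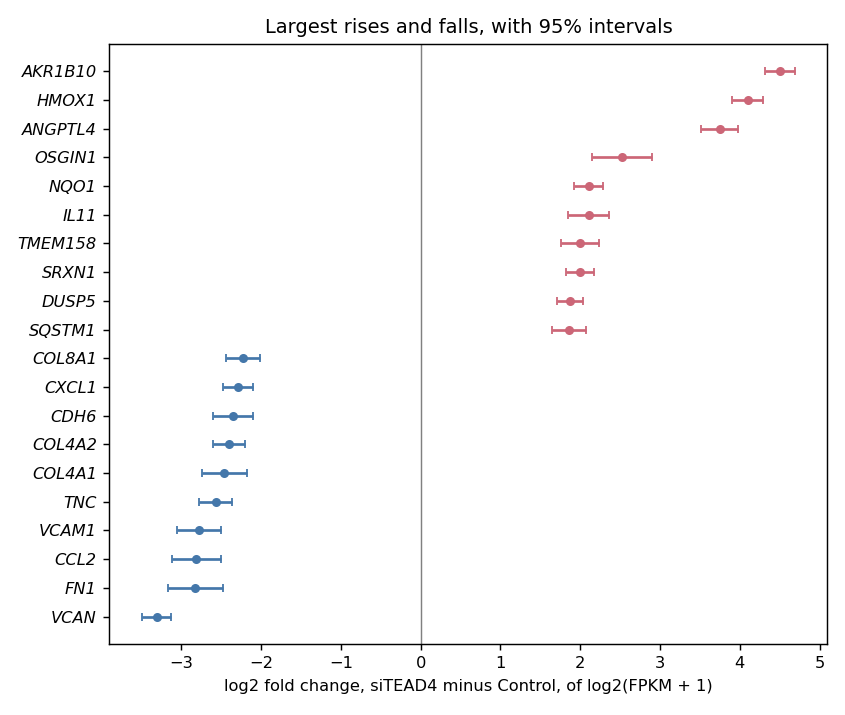
Log2 fold change of log2(FPKM + 1), siTEAD4 minus Control (horizontal axis), for the 10 largest rises and the 10 largest falls; points are limma estimates and bars 95% confidence intervals, with 3 libraries per group. The rises run from 1.86 for SQSTM1 to 4.50 for AKR1B10, and the falls from -2.23 for COL8A1 to -3.31 for VCAN.

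In all, 5123 of 11411 genes tested passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 2982 of them higher and 2141 lower in siTEAD4. Most of the changes were small: 471 genes passed with an absolute log2 fold change of at least 1, 99 higher and 372 lower. Higher genes made up 58.2% of the calls on the deposited values, 46.9% after each library was rescaled to one median and 46.5% after TMM-like scaling, so the balance of small rises and falls depended on the scaling. The groups did not overlap in 6588 tested genes, 57.7% of them, where chance gives 10% for 3 against 3.

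Genes that NF-kB induces fell, while those encoding its subunits and the IKK complex were mixed. These lists overlap, since RELB, NFKB1 and NFKB2 belong to both. Of 29 tested NF-kB target genes, 19 fell and 1, TRAF1, rose (0.45, adjusted p = 0.00273); adjusted over the list alone, 20 fell and 1 rose, and without Control 2 the counts were 22 and 3. The median log2 fold change was -0.86. VCAM1 and ICAM1, which encode adhesion molecules for leukocytes, went from 271 ± 46.0 to 38.3 ± 1.95 FPKM and from 70.0 ± 6.42 to 15.0 ± 0.556 FPKM (SD, n = 3). Among the other genes fixed in advance, CXCL1 (-2.29), BIRC3 (-1.79), TNFAIP3 (-1.10), CXCL8 (-1.08) and NFKBIA (-0.83) fell. IL6 was at 33.3 ± 2.63 and 28.4 ± 0.323 FPKM and did not pass (-0.22, adjusted p = 0.0581), although it passed in 6 alternatives, among them those without Control 1 (adjusted p = 0.0146), without Control 2 (0.0342) and after rescaling to one median (0.0236). The list passed camera (adjusted p = 4.13e-10), but not with an estimated correlation (adjusted p = 0.0553), except with length and GC trends removed (0.0272). The list of NF-kB subunits and the IKK complex held 9 genes, among them NFKBIB, which encodes an inhibitor of NF-kB. In it, RELA (-0.84) and RELB (-0.36) fell, and CHUK (0.73), IKBKG (0.49) and IKBKB (0.24, adjusted p = 0.0469) rose. Adjusted over the list alone the numbers were likewise 3 higher and 2 lower. The list did not pass camera (adjusted p = 0.847, and 0.920 with an estimated correlation). The call of RELB ended without Control 3 or any 1 siTEAD4 library (adjusted p from 0.069 to 0.145), that of IKBKG without Control 3, siTEAD4 1 or siTEAD4 2 (0.0524 to 0.0823) and after rescaling to one median (0.0531), and that of IKBKB without Control 3 or any 1 siTEAD4 library (0.135 to 0.145) and after that rescaling (0.122).

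Target genes of YAP and TEAD did not move together. Of 21 tested, 4 rose and 6 fell, and adjusted over the list alone the counts were also 4 and 6. CRIM1 (-1.67), CCDC80 (-1.53), IGFBP3 (-1.51), AXL (-1.10), TGFB2 (-1.04) and RBMS3 (-0.61) fell, and F3 (1.25), GADD45A (0.98), ANKRD1 (0.57) and LATS2 (0.32, adjusted p = 0.0338) rose. IGFBP3, which encodes a secreted binding protein of insulin-like growth factors, went from 1353 ± 36.7 to 473 ± 4.08 FPKM (SD, n = 3). The widely used targets CCN1 (0.08, adjusted p = 0.407) and CCN2 (0.03, adjusted p = 0.812) did not pass, with 95% intervals of -0.09 to 0.26 and -0.20 to 0.27 on the log2 scale. The list's median log2 fold change was 0.03, its mean -0.18 and camera's direction down, without passing (adjusted p = 0.385), and the median was -0.03 after each of the 2 rescalings. With length and GC trends removed, 7 rose and 6 fell. The call of LATS2 ended without any 1 siTEAD4 library (adjusted p from 0.0908 to 0.111) and after rescaling to one median (0.0592). Among 21 Hippo pathway genes, TEAD4, WWC1 (-0.57) and AMOT (-0.42) fell and MAP4K4 (0.43), STK4 (0.43), MOB1B (0.42) and LATS2 rose; adjusted over the list alone, 3 rose and 3 fell. Its median was 0.09, its mean 0.02 and camera's direction down (adjusted p = 0.889). The call of AMOT ended without siTEAD4 1 (adjusted p = 0.0517), that of STK4 without Control 3 or any 1 siTEAD4 library (0.0618 to 0.109) and that of MOB1B without any 1 library but Control 1 (0.0588 to 0.158) and after rescaling to one median (0.0802). TMM-like scaling also ended that of STK4 (0.0575). The Hippo counts were 2 higher and 4 lower after rescaling to one median, 1 and 4 after TMM-like scaling, 7 and 4 without Control 1, and 1 higher with 2 or 3 lower without any 1 siTEAD4 library.

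Extracellular matrix genes fell as a group. Of 25 tested, 23 fell and none rose by limma at this threshold, and adjusted over the list alone 24 fell; the median log2 fold change was -1.40. Type IV collagen genes of the basement membrane, COL4A1 and COL4A2, went from 40.5 ± 6.81 to 6.45 ± 0.334 FPKM and from 57.4 ± 4.16 to 10.04 ± 0.674 FPKM (SD, n = 3). The tenascin gene TNC fell from 60.2 ± 6.18 to 9.27 ± 0.271 FPKM. The members that did not pass were TIMP1 (-0.10, adjusted p = 0.492) and MMP1 (-0.70, adjusted p = 0.0761). MMP1 passed without siTEAD4 3 (-1.11, adjusted p = 0.000696) and with length and GC trends removed (-0.85, adjusted p = 0.024). Camera gave an adjusted p of 2.82e-19, and 0.0211 with an estimated correlation. The latter call ended without any 1 library (0.0521 to 0.0790) and with length and GC trends removed (0.0627), settings chosen after seeing the data. The list's median held in these settings, at -1.49 to -1.39 without 1 library and -1.32 with the trends removed. Of 17 genes of the TGF-beta response, 13 fell and 1, SKIL, rose (0.45), with the same counts adjusted over the list alone and a median of -0.46. TGFBI (-1.40), ID3 (-1.38) and ID1 (-1.35) led the falls. That list passed camera (adjusted p = 3.38e-05), but not with an estimated correlation (adjusted p = 0.0907).

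The integrin genes ITGAV, ITGB1 and ITGA5 (-0.81) fell within the actin and focal adhesion list, where 8 of 24 genes fell and 2, PDLIM5 (0.35) and LIMA1 (0.55), rose, also when adjusted over the list alone. Without Control 2, 7 rose and 9 fell, and with length and GC trends removed 9 rose and 9 fell. ITGAV went from 105 ± 38.6 to 29.4 ± 0.661 FPKM and ITGB1 from 734 ± 196 to 260 ± 8.59 FPKM (SD, n = 3). The list did not pass camera (adjusted p = 0.124; 0.532 with an estimated correlation). Genes of renal tubule and ccRCC identity fell in 8 of 10 cases and rose in 1, EPAS1 (0.32, adjusted p = 0.035), with the same counts adjusted over the list alone and a median of -0.95. They included the kidney cadherin gene CDH6 (-2.35), CP (-1.85) and EGFR (-1.29). The call of EPAS1 ended without Control 3 or any 1 siTEAD4 library (adjusted p from 0.0856 to 0.113) and after rescaling to one median (0.0755). For the list, camera gave an adjusted p of 2.09e-05, and with an estimated correlation one of 0.0521. Of 9 epithelial junction and keratin genes, CDH6, CLDN1 (-1.07), EPCAM (-0.88) and KRT19 (-0.67) fell and CLDN4 rose (0.79), and adjusted over the list alone 4 fell and 2 rose; the list did not pass camera (adjusted p = 0.085; 0.241 with an estimated correlation). Among 7 mesenchymal transition regulators, CDH2 fell (-1.40) and SNAI2 (1.29) and ZEB1 (0.67) rose, also when adjusted over the list alone (camera adjusted p = 0.889).

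Genes of mitosis fell and those of DNA replication did not move together. Of 25 G2/M genes, 21 fell and none rose in limma, 23 fell adjusted over the list alone, and the median was -0.50. KIF20A went from 62.8 ± 4.01 to 29.3 ± 0.878 FPKM and the proliferation marker MKI67 from 40.1 ± 7.95 to 19.6 ± 0.271 FPKM (SD, n = 3). The G2/M list passed camera (adjusted p = 4.13e-10), also with an estimated correlation (0.0211), but by the estimate not without any 1 library (0.0521 to 0.0960). Its median stayed at -0.52 to -0.43 when 1 library was left out. Of 26 S-phase and replication genes, 9 rose and 3 fell, also when adjusted over the list alone: the thymidylate synthase gene TYMS (-1.24) and RRM2 (-0.26) were among those that fell, and CCNE1 (0.60) and CDC6 (0.58) rose. The call of RRM2 ended without any 1 siTEAD4 library (adjusted p from 0.0701 to 0.0992). The list did not pass camera (adjusted p = 0.954), with a median of 0.01 (-0.06 after rescaling to one median), a mean of 0.05 and camera's direction down. The excess of rises depended on the scaling: 6 rose and 6 fell after either rescaling, and 11 rose and 8 fell with length and GC trends removed. Without 1 siTEAD4 library, 3 to 5 rose and 2 fell.

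Sterol and fatty acid synthesis genes fell in 16 of 23 cases and rose in none by limma, with the same counts adjusted over the list alone and a median of -0.63. SREBF1, which encodes a transcription factor of lipid synthesis, went from 16.8 ± 1.36 to 6.30 ± 0.101 FPKM (SD, n = 3), and DHCR7 (-1.19) also fell. This list passed camera with the preset (adjusted p = 6.89e-09) and with an estimated correlation (0.0211), but by the estimate not without any 1 library (0.0521 to 0.0790). Its median stayed at -0.64 to -0.61 when 1 library was left out. Of 22 interferon response genes, 10 fell and none rose, also when adjusted over the list alone, with a median of -0.30; IFIT1 went from 8.64 ± 0.232 to 4.47 ± 0.0208 FPKM (SD, n = 3), and OAS1 (-0.77) and OAS3 (-0.59) fell. Camera gave an adjusted p of 0.000111, which was 0.0521 with an estimated correlation and 0.0490 with length and GC trends also removed.

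Most heat shock, immediate early and amino acid response genes rose, the last less firmly. Of 12 heat shock genes, 10 rose and none fell, also when adjusted over the list alone, with a median of 0.70. HSPA8, a constitutive chaperone gene, went from 784 ± 57.1 to 1640.5 ± 40.7 FPKM (SD, n = 3). HSPA1B rose by more (1.74), but it is nearly identical in sequence to HSPA1A (0.75), so the split between the pair is uncertain. Of 19 AP-1 and immediate early genes, 13 rose and none fell, also when adjusted over the list alone, with a median of 0.74; without Control 2, 14 rose and 2 fell. The phosphatase gene DUSP5 went from 16.1 ± 0.618 to 61.5 ± 1.19 FPKM, and SPRY2 (1.15), SPRY4 (1.12) and MYC (1.04) rose; SPRY4 was at 0.353 ± 0.0896 FPKM in Control, so its fold change is understated. The heat shock (adjusted p = 0.000288) and AP-1 lists (9.4e-05) passed camera, but not with an estimated correlation (adjusted p = 0.0768 and 0.0751). Of 17 ATF4 and amino acid response genes, 11 rose and 3, PSPH (-0.33), SLC7A5 (-0.27) and CEBPB (-0.36), fell, also when adjusted over the list alone, with a median of 0.37. ASNS, which makes asparagine, went from 31.9 ± 1.65 to 117 ± 3.61 FPKM, and PSAT1 (1.49) and SLC7A11 (1.09) rose. The call of CEBPB ended without Control 3 or any 1 siTEAD4 library (adjusted p from 0.0869 to 0.146), and that of SLC7A5 without any 1 siTEAD4 library (0.0806 to 0.121). This list was at the edge of camera's threshold (adjusted p = 0.0356): the value was 0.318 with an estimated correlation, 0.0776 without Control 1 and 0.081 with a filter of 5 FPKM.

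Several lists held genes that rose beside genes that fell. Of 21 HIF target genes, 11 rose, led by ANGPTL4 (3.75) and NDRG1 (1.33), and 3 fell, among them SLC2A1 (-0.60) and LOX (-0.65); adjusted over the list alone 11 rose and 4 fell, the median was 0.37 and camera's adjusted p 0.109 (0.249 with an estimated correlation). Of 21 p53 target genes, 8 rose, led by GDF15 (1.21), AEN (1.12) and GADD45A (0.98), and DDB2 (-0.86) and BBC3 (-0.44) fell (camera adjusted p = 0.327), with the same counts adjusted over the list alone. Of 16 genes of ER chaperones and the unfolded protein response, 6 rose, among them SDF2L1 (1.28), CRELD2 (1.12) and MANF (1.00), and 6 fell, among them SEL1L (-1.06), also when adjusted over the list alone (camera adjusted p = 0.847, direction down, median -0.07 and mean 0.06). Of 20 apoptosis regulators, 6 rose, among them PMAIP1 (0.91) and BAK1 (0.72), and BIRC3, BCL2L11 (-0.72), BBC3, BID (-0.32) and CFLAR (-0.25) fell, also when adjusted over the list alone (camera adjusted p = 0.889). Of 19 glycolysis genes, HK1 (0.33), HK2 (0.44), GPI (0.31), PFKP (0.47) and ALDOA (0.47) rose and the glucose transporter gene SLC2A1, SLC16A1 (-0.35) and SLC16A3 (-0.52) fell, also when adjusted over the list alone (camera adjusted p = 0.954, direction down, median 0.07). Calls within these lists that ended when 1 library was left out were, among others, those of ALDOA, GPI, HK2, SLC16A1, BBC3, BID and CFLAR. Several different libraries ended each call, so no single library decided it. Log2 fold changes in those fits were 0.42 to 0.49 for ALDOA, 0.29 to 0.33 for GPI and 0.42 to 0.45 for HK2. They were -0.38 to -0.32 for SLC16A1, -0.41 to -0.40 for BBC3, -0.37 to -0.23 for BID and -0.27 to -0.20 for CFLAR. Without Control 3 or any 1 siTEAD4 library the adjusted p was 0.0596 to 0.0858 for ALDOA and 0.0616 to 0.0916 for GPI, and without any 1 siTEAD4 library it was 0.0676 to 0.0804 for HK2. After rescaling to one median, ALDOA (0.0620) and GPI (0.0844) also lost their calls, which left 3 glycolysis genes higher and 3 lower, and without any 1 siTEAD4 library 2 were higher. Without Control 3, siTEAD4 1 or siTEAD4 2 it was 0.0692 to 0.103 for SLC16A1, and without Control 3, siTEAD4 2 or siTEAD4 3 it was 0.0859 to 0.095 for BBC3. The call of BID ended without any 1 library but Control 1 (0.0516 to 0.175), and that of CFLAR without any 1 library but Control 2 (0.0596 to 0.132). Without Control 3 or any 1 siTEAD4 library, 2 or 3 apoptosis genes fell instead of 5, and 1 to 3 HIF target genes, which was 5 after TMM-like scaling. With length and GC trends removed, 9 apoptosis genes rose and 8 fell.

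Of 7 tested replication-dependent histone genes, H4C8 (1.04), H2AC6 (0.87), H2BC4 (0.74) and H2BC12 (0.54) rose, also when adjusted over the list alone (camera adjusted p = 0.109; 0.355 with an estimated correlation). Histone genes share sequence with close copies, so their single values are uncertain, and the call of H2BC12 ended without Control 3 (adjusted p = 0.0519) and without siTEAD4 1 (0.0515), where 2 of 6 histone genes rose. Of 31 ribosomal protein genes, RPL5 (0.34) and RPL4 (0.30) passed, none when adjusted over the list alone, and of 27 nuclear oxidative phosphorylation genes NDUFA1 (0.32) passed, none when adjusted over the list alone. Neither list passed camera (adjusted p = 0.109 and 0.36). With an estimated correlation the values were 0.920 and 0.933. Without Control 2, both lists passed at medians of 0.34 (adjusted p = 0.000459) and 0.20 (adjusted p = 0.0235), with 25 of 31 and 16 of 27 genes higher, but neither did with an estimated correlation (adjusted p = 0.516 and 0.464), a test chosen after seeing the data. The calls of RPL5, RPL4 and NDUFA1 ended after rescaling to one median (adjusted p = 0.0769, 0.133 and 0.0865). They also ended without Control 3 or any 1 siTEAD4 library for RPL5 (0.0594 to 0.0867), without any 1 library but Control 2 for RPL4 (0.0536 to 0.114), and without Control 3, siTEAD4 1 or siTEAD4 2 for NDUFA1 (0.0657 to 0.121).

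Most markers of other cell types were low in both groups, but not all. The highest leukocyte marker was CD68, at 31.7 ± 5.95 FPKM in Control and 20.01 ± 1.24 FPKM in siTEAD4 (SD, n = 3), while the median marker of 13 found stood at 0.133 and 0.0300 FPKM. Of 3 leukocyte markers tested, CD68 (-0.62), LAPTM5 (-0.63) and CSF1R (-0.33) fell, and the call of CSF1R ended without any 1 library but Control 1 (adjusted p from 0.0694 to 0.173). LUM (-0.81) and ACTA2 (-0.59) were the 2 fibroblast and pericyte markers tested and both fell, and EGFL7, the only endothelial marker tested, did not pass (-0.22, adjusted p = 0.265), except without Control 1 (-0.40, adjusted p = 0.0178). These lists held fewer than 5 tested genes and had no set test at this filter, and for each of the 3 the counts adjusted over the list alone were the same. Of 13 mitochondrially encoded genes, 0 were among the symbols analysed here.

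**Figure D3:**
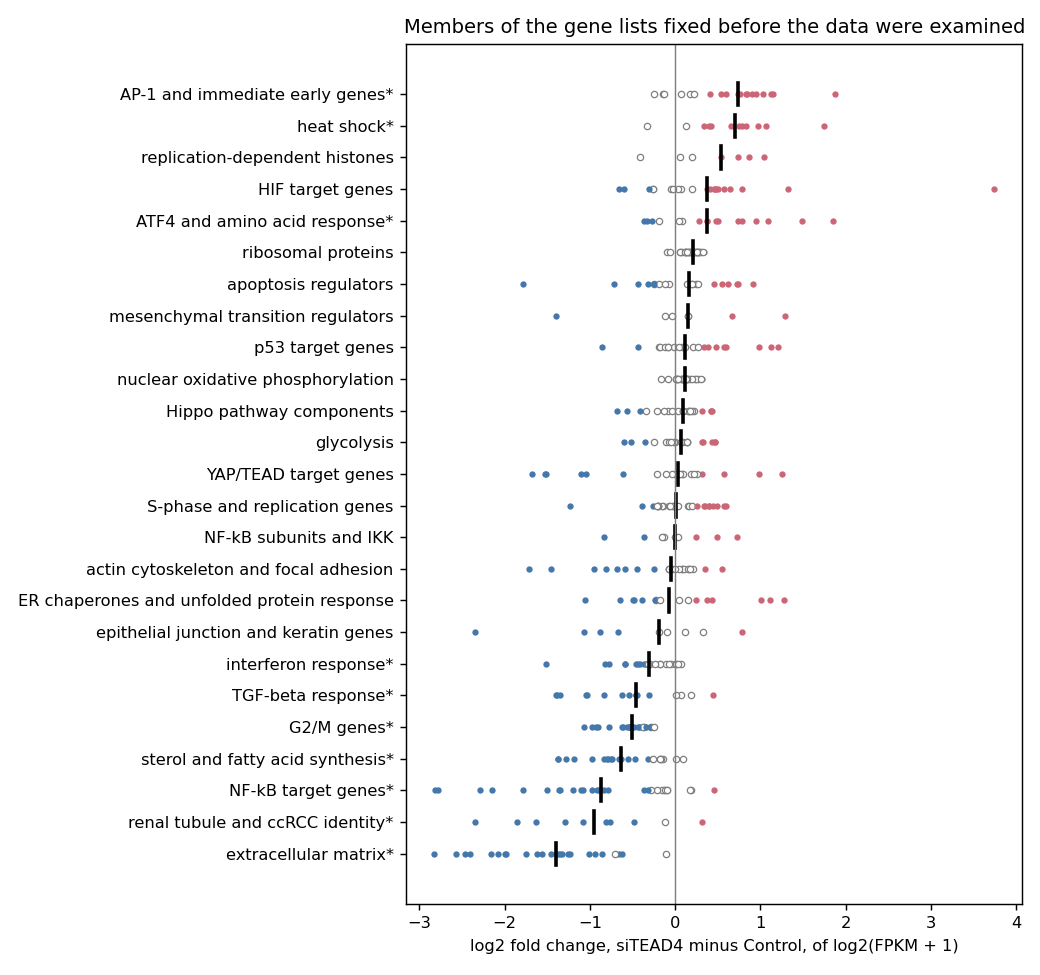
Log2 fold change of log2(FPKM + 1), siTEAD4 minus Control (horizontal axis), of each tested member of the 25 gene lists (vertical axis), ordered by median; filled points passed limma's adjusted p of 0.05 (red higher, blue lower), open points did not, black bars are list medians and an asterisk marks an adjusted camera p under 0.05. Medians run from -1.40 for the extracellular matrix to 0.74 for AP-1 and immediate early genes.

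The Control libraries differed more among themselves than the siTEAD4 libraries did: the median SD of log2 values was 0.160 against 0.0607, and the deviations of Control 1 and Control 2 from their group mean followed GC content (Spearman's rho -0.656 and 0.693) and transcript length (0.623 and -0.577) across genes. The count of changed genes rested on these few libraries, with 3403 genes past the threshold without siTEAD4 1 and 3594 without Control 3, against 5123. Genes higher numbered 1786, 1855 and 1851 without siTEAD4 1, 2 and 3 in turn and 2055 without Control 3, against 2982. Of the 25 lists, 10 passed camera with its preset correlation and 3 (extracellular matrix, G2/M and sterol synthesis) with an estimated one. Without any 1 library, the estimate gave 0 lists, while the medians of these 3 lists held, as given above for each. Any left-out library also cost that test degrees of freedom, so these losses do not show that the lists rested on single libraries. With the preset, other splits of the 6 libraries into 3 and 3 gave 6 to 14 lists, and with the estimate 0. Each of those splits still holds unequal numbers of both groups. Their counts are therefore not what either form of camera would give without a group difference.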

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

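TEAD4 passed the threshold, and was lower, in each of the 17 alternatives fitted over all genes, with log2 fold changes from -0.79 to -0.50 and adjusted p from 0.000417 to 0.0276. No named gene or list reversed its call in any alternative. Of the 168 genes picked for naming and tested, 137 had the same outcome in all alternatives that were run, as did 8 of the 25 lists. Those 8 were all lists that did not pass as reported. Each of the 10 lists that passed lost its call in at least 1 alternative. With the preset correlation, only the ATF4 list lost its call in the 17 alternatives fitted over all genes. Its camera adjusted p was 0.081 with a filter of 5 FPKM and 0.0776 without Control 1. The other lists that passed lost their calls only with an estimated correlation. The number of changed genes was 5123 and lay between 3403 and 6547 when 1 library was left out (3403 without siTEAD4 1 and 6547 without Control 2), and genes higher between 1786 and 4025. Lower counts came without any 1 siTEAD4 library, from the group with the smaller spread. Leaving out Control 3, from the group with the larger spread, also gave a low count of 3594, with 2055 higher. What lowered these counts was not tested. The stricter thresholds by construction called fewer: an absolute log2 fold change of at least 1 left 471 genes (99 higher, 372 lower), and an adjusted p under 0.01 left 3087, 1601 of them higher. With an estimated correlation camera called 3 lists instead of 10; with this estimate, in settings chosen after seeing the data, it called 4 with length and GC trends removed (NF-kB targets, G2/M, interferon and sterol) and 0 without each of the 6 libraries in turn. On all 6 libraries, the estimated correlations of the G2/M (-0.00219), sterol (-0.0307), interferon (-0.0288) and renal lists (-0.0631) lay below the preset 0.01. A higher correlation therefore does not account for their larger adjusted p by the estimate. For the other lists called with the preset, the estimated correlation lay above 0.01. The estimated form also takes its degrees of freedom from the libraries instead of the genes, which raises its p-values at any correlation. How much of each loss came from this was not tested. Removing each library's length and GC trend, chosen after seeing the data, gave 6809 genes, of which 4818 were among the 5123 called on the deposited values in the same direction. With the replicate block the fit called 5180 genes; same-numbered libraries' deviations correlated at -0.163, 0.272 and 0.0896 across genes, not every library correlated best with its own number, and the numbers were not taken as pairs. The block changed no call of a list; among named genes it ended those of IKBKB (adjusted p = 0.0883) and CFLAR (0.0648), and MMP1 passed (0.00689). Camera without the low-value filter also called the HIF (adjusted p = 0.05 when rounded) and ribosomal protein lists (0.0484), and the leukocyte marker list (0.0155), which only then had enough tested genes. Fry, which asks whether a list's genes move one way without comparing them with other genes, also called the p53, HIF, actin, epithelial junction and histone lists. Depth is unknown, so precision rests on the 3 libraries per group alone.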

Other observations

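The gene lists in this part, the removal of length and GC trends and the use of an estimated correlation with that removal or without a library were chosen after the data had been seen, as were the test of a compound treatment and both tests of the Control libraries; the tests of the extracellular matrix genes and of other splits were set before their results were seen.

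Genes of the oxidative stress response that NRF2 is known to induce were higher in the siTEAD4 libraries in 26 of 28 cases tested, with a median log2 fold change of 1.29, and 1, ABCC1, was lower (-0.68). Besides AKR1B10 and HMOX1, they included the glutathione synthesis genes GCLM (1.47) and GCLC (1.26), the thioredoxin reductase gene TXNRD1 (1.73) and the ferritin light chain gene FTL (1.54). Camera over the 6 added lists gave an adjusted p of 3.98e-13, and 0.0366 with an estimated correlation, but the list was written after several of its genes had been seen to rise. Pentose phosphate pathway genes rose in 6 of 8 cases (median 0.64), with PGD at 1.23 (camera adjusted p = 0.0012; 0.0411 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetase genes rose in 15 of 18 cases (median 0.66), among them WARS1 (1.29) and GARS1 (0.97), at camera adjusted p = 1.34e-06 and, with an estimated correlation, 0.0411. Proteasome subunit genes rose by less, in 16 of 27 cases (median 0.30), led by PSMD12 (0.63) and PSMC2 (0.60), at camera adjusted p = 0.00016, which was 0.196 with an estimated correlation. By the estimate, none of the added lists passed without Control 2 (adjusted p of at least 0.105). The oxidative stress list passed without Control 1 or Control 3 and the synthetase list without Control 3, but neither without any 1 siTEAD4 library, and the pentose phosphate list passed only with all 6 libraries; with length and GC trends removed, the synthetase (0.123) and pentose phosphate lists (0.0571) did not pass by the estimate.

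Complement and acute phase genes fell in 12 of 13 cases, with a median of -1.34. The central complement gene C3 had a log2 fold change of -2.46, SAA2 one of -1.72 and SERPINA1 one of -1.28; camera gave an adjusted p of 8.35e-11, and 0.0226 with an estimated correlation, which was 0.105 without Control 2 and 0.0366 to 0.0479 without 1 other library. Autophagy and lysosome genes went both ways: 8 of 25 rose, among them SQSTM1 (1.86), WIPI1 (1.29) and MAP1LC3B (1.01), and 6 fell, among them the lysosomal membrane genes LAMP2 (-1.06) and LAMP1 (-0.99), so the list did not pass camera (adjusted p = 0.975).

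The fall of the extracellular matrix genes was weighed against technical explanations because these transcripts are long, with a median of 5102 bases against 3423 for all tested genes. With each library's length and GC trend removed, the list's median was -1.32 against -1.40 and 24 of 25 genes fell (camera adjusted p = 6.21e-16; 0.0627 with an estimated correlation), and the median and the number of genes argue against that trend as the whole cause. Without Control 2, the library farthest from the rest of its group, the median was -1.49 and 20 of 22 genes fell (camera adjusted p = 3.44e-17; 0.0790 with an estimated correlation), and the median and the number of genes argue against that library alone. On all libraries the estimate gave 0.0211, so either change ended the call by that test. Leaving out Control 2 also left that test fewer degrees of freedom, and what else ended the call was not tested. A difference in handling between the groups was not tested, and the labelled treatment stays open, so the fall may be an effect of the treatment as a hypothesis only.

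The rise of the oxidative stress genes was weighed in the same way. With the length and GC trend removed their median was 1.26 against 1.29 and 26 genes were higher (0.0296 by camera with an estimated correlation), which argues against that trend. The column headers name an inhibitor and a vehicle, and a reactive compound could raise such genes, as could transfection or the loss of TEAD4. TEAD4 itself ranked within the lowest 7.3% of fold changes, lower but far from the largest fall, and this separates neither treatment from the other, since a compound can also lower the mRNA. The siRNA and a compound cannot be told apart here because every library of one group differs from the other group in the same way.

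The spread between the Control libraries followed properties of the transcripts. Control 2 stood higher than Control 1 by a median of 0.37 on the log2 scale in the shortest 10% of transcripts and was at -0.40 relative to it in the longest 10%. Of the variance of Control 2's deviation from its group mean across genes, length beyond GC removed 13.5 percentage points and GC beyond length 26.6, and both together removed 58.4%, as a difference in RNA fragmentation or library preparation would; no biological explanation was tested. With the trends removed, the median SD of the Control libraries was 0.0926 instead of 0.160, still above the 0.0521 of the siTEAD4 libraries.

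Of the 10 splits of the 6 libraries into 3 and 3, the real one called 5123 genes and 1 split, itself, reached that number; the highest other split called 0 genes by limma at an adjusted p under 0.05 (8 to 327 at an unadjusted p under 0.05). For gene lists, 4 of the 10 splits called as many as the real one, which called 10, and the highest other split called 14. With length and GC trends removed, the real split again called 10 lists, the other splits called 6 to 13, and 3 of them called at least 10. The 2 splits with 14 lists, which set Control 2 apart from Control 1 and Control 3, then called 8 each, but the remaining split of that kind went from 9 to 10. The trends therefore do not account for the lists called in other splits. Each of the other splits still holds unequal numbers of both groups, and 10 splits are too few for a share under 0.05.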
